A study of Mus musculus with 6 samples.

How the data were processed

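Expression had been measured on 6 Affymetrix arrays, 3 of the immunoprecipitated fraction (IP) and 3 of the unbound fraction (UB), with the fractions of a preparation carrying the same replicate number. Per the labels, the tissue was the dissected habenula of adult mice aged 6 to 12 weeks of the Chat DW167 line. Ribosomes were affinity purified, and RNA was extracted with Trizol, treated with DNase and cleaned on columns. Starting from 20 ng, RNA was amplified over 2 cycles and labelled with biotin.

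The deposited values are log2 expression levels per probe set that the authors made with GCRMA, which corrects for background, normalizes by quantiles and summarizes the probes of a probe set. The version of GCRMA is not given in the sources used here. The authors state that replicates were normalized within groups. In the files, the lowest value differed between the IP and UB arrays and was shared within each, so the fractions had been normalized apart. Whether a scaling between them followed cannot be told from this. The authors recommend a scaling between groups on the biotinylated controls. The table held 17370 probe sets, of which 64 were controls, 16464 carried a gene symbol and 842 carried none and are unnamed here. Each gene had 1 probe set. Gene identifiers were matched to the RefSeq table of assembly GRCm38.p6 for names only, and all 16464 matched.

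The offset between fractions was the mean difference of 18 biotinylated control probe sets (IP minus UB 0.016 on the log2 scale, SE 0.031 over control probe sets and 0.212 over arrays, SD over control probe sets 0.13), and it was subtracted from the IP arrays. Probe sets were tested if at least 3 of the 6 arrays had a level of 50 or more on the linear scale as deposited (log2 5.644), whatever the fraction. This left 8960 probe sets, 8603 of them with a gene symbol, and 8346 others were not tested. GCRMA gave many probe sets an equal value on all arrays of a fraction: 50.6% of the table in IP and 47.7% in UB, and 1789 and 1578 of the tested probe sets.

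The fractions were compared with limma (version 3.58.1 in R 4.3.3), with moderated variances following the mean level (0.651 prior degrees of freedom), two-sided and adjusted by Benjamini-Hochberg over the tested probe sets. A call was an adjusted p under 0.05. Without adjustment, 6859 probe sets had p under 0.05. Where all 3 arrays of a fraction were under 50, the fold was computed against 50 and is written as at least that fold, and no fold is given where both fractions were under 50. Such bounds hold at the control offset only, and bounds near 1 rest on it. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

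Before the data were examined, 31 gene lists were fixed: cholinergic transmitter genes, nicotinic receptor subunits, HCN pacemaker channels, muscarinic receptors, markers of the habenula, dorsal medial habenula, lateral habenula, thalamus, and hippocampal and cortical excitatory neurons, genes of glutamate, GABA and monoamine transmission, neuropeptides and their receptors, ionotropic and metabotropic glutamate receptors, GABA receptors, sodium, calcium and potassium channels, pan-neuronal markers, markers of astrocytes, oligodendrocytes, their precursors, microglia, endothelial and mural cells, ependyma and choroid plexus, and blood, immediate early genes, ribosomal protein genes and nuclear genes of the respiratory chain. Lists with at least 3 tested genes, 27 in all, were compared with all other genes by camera in limma with a preset correlation of 0.01 between genes, adjusted over the 27 lists. Camera was also run with an estimated correlation. A further 20 gene families, defined by their symbols, were chosen after the data were seen and adjusted among themselves.

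The genes named were set by a rule: the 10 largest increases and the 10 largest decreases among called genes whose fractions did not overlap, all measured members of the cholinergic, nicotinic and HCN lists, the 4 tested members of each other list with the largest change, and the gene of the tagged ribosomal protein, which was not analysed here. Other genes were chosen after their values were seen.

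Both steps were tested on simulated data made from the spread of these arrays. With 8760 unchanged probe sets, limma made 0 false calls when the offset was known, and 101 when the controls had a spread of 0.13, of which 89 were tied probe sets and 0 reached 2-fold. The spread of the controls from array to array was not simulated. Unchanged probe sets were given the same mean level in both fractions, so false calls from normalizing the fractions apart were not tested either. Limma recovered 50%, 60%, 86% and 98% of changes of 0.5, 1, 2 and 4 on the log2 scale in the second case. Camera with the preset correlation called a list of 12 probe sets shifted by 2 on the log2 scale (adjusted p = 2.24e-15) and 0 of 199 unshifted lists, 3 of which had an unadjusted p under 0.05. The simulated residuals had random signs and the lists were random, so their genes did not vary together. False calls of lists whose genes do so were thus not tested. Estimated correlations in the real lists ran from -0.198 (lateral habenula) to 0.377 (GABA receptors), against the preset 0.01. With an estimated correlation it did not call the shifted list (adjusted p = 0.166), so that version could not call lists of that size and shift at this number of arrays.

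The same replicate number in both fractions was checked as a pairing. The deviations of an array from its fraction's mean had r across probe sets of 0.592, 0.483 and 0.279 between equal replicate numbers, where genes are not independent replicates, and IP replicate 3 went best with UB replicate 2 (0.315). The r of equal replicate numbers was positive in all 3 cases, so the fractions of a preparation varied together to some degree. The main fit had no block, as planned, and so ignored this pairing. The replicate number was a block only in an alternative, which gave 2911 probe sets higher and 3963 lower.

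The alternatives tried were 5 other scalings set in advance (values as deposited, equal medians of all probe sets, quantile normalization, the control offset as a median or per array), no filter or a filter at 200, a pseudocount of 16, no variance trend, the replicate block, each array left out in turn, and a threshold from glial markers. After the data were seen, 4 more were added: both arrays of replicate 1 left out, probe sets tied in both fractions left out, levels under 50 raised to 50, and equal medians of the tested probe sets. Without 1 array its partner stayed in the unpaired fit, so variation shared by a pair could count there as a difference or as spread. Precision is limited by the 3 arrays per fraction.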

Results

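Expression was measured on 6 Affymetrix arrays of RNA from the dissected habenula of adult mice. The mice carried a bacterial artificial chromosome that puts a tagged ribosomal protein under the control of the choline acetyltransferase gene, so that ribosomes of cholinergic neurons can be pulled down with their messenger RNA (translating ribosome affinity purification, TRAP). The 3 IP arrays hold the immunoprecipitated RNA of cholinergic neurons of the medial habenula, and the 3 UB arrays hold the unbound RNA left in the same preparations, which stands for the whole dissected tissue. Levels are deposited log2 values, given as mean ± SD over 3 arrays, and log2 fold changes of IP over UB are given ± SE. An array with a level of 50 or more on the linear scale counts as having signal. That held for 7533, 7563 and 7579 probe sets on the IP arrays and for 8618, 8659 and 8627 on the UB arrays. The 6 arrays, 3 per group, limit the precision of every value. Genes marked † were chosen after their values were seen, and all others by a rule set before the data were examined.

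The comparison of IP with UB asks which transcripts the cholinergic neurons of the medial habenula carry on their ribosomes more, or less, than the tissue around them does. Slc18a3, the vesicular acetylcholine transporter, was at least 68.8-fold higher in IP. The nicotinic receptor subunits Chrna3 and Chrnb4 were 16-fold and 15.1-fold higher. Transcripts of other cells of the tissue were far lower in IP: the myelin gene Mog was at least 32.7-fold lower. The astrocyte gene S100b was at least 29.8-fold lower, and Gad1, which makes the transmitter GABA, at least 30.7-fold lower. Of 8960 probe sets tested, 1285 were called higher in IP by at least 2-fold and 2513 lower by at least 2-fold (limma, adjusted p under 0.05).

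**Figure D1:**
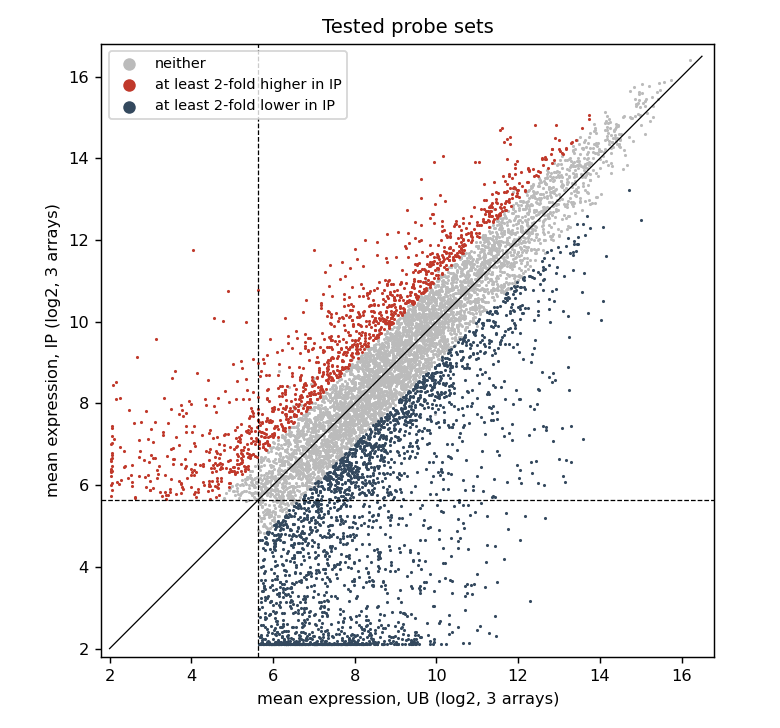
Mean expression of each tested probe set on the 3 UB arrays (x axis, log2) and on the 3 IP arrays (y axis, log2), with the line of equal levels and dashed lines at the level of 50 (log2 5.644). Red points mark the 1285 probe sets called at least 2-fold higher in IP and dark points the 2513 called at least 2-fold lower, of which 1302 were under 50 on all 3 IP arrays.

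Without the fold limit, 2772 probe sets were called higher and 3900 lower, and 2288 were not called. The 3 IP values lay all above or all below the 3 UB values for 7183 probe sets (80.2%). Chance would give 10% for untied values of arrays normalized together. Here the fractions were normalized apart, and 587 probe sets had 1 value on all 3 arrays of both fractions. Processing alone can part such values, so the excess over 10% does not measure biology. The share of the 2-fold calls that were higher, 33.8%, rested on the scaling between the fractions: it was 81.6% with the median of all probe sets made equal (a shift of 1.55 on the log2 scale), 49.5% with the median of the tested probe sets made equal (0.34) and 49.0% with quantile normalization (0.33). With both arrays of replicate 1 left out, 1163 probe sets were at least 2-fold higher and 2672 lower.

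Members of the list of cholinergic transmitter genes went both ways. Slc18a3 (probe set 20508_at) stood at 11.76 ± 0.62 in IP and at 4.05 ± 0.22 in UB (adjusted p = 2.88e-05). Slc5a7 (63993_at), the high-affinity choline transporter, stood at 6.31 ± 0.13 in IP against the lowest level of the table in UB, and was at least 1.57-fold higher (adjusted p = 5.80e-07). The choline transporter-like gene Slc44a1 and the choline kinase gene Chka were 18.6-fold and at least 3.33-fold lower in IP. Ache (11423_at), the acetylcholinesterase gene, differed by -0.68 ± 0.55 and was not called (adjusted p = 0.314). It was called lower with the replicate number as a block (adjusted p = 0.0270) and with the control offset per array (adjusted p = 0.0427), over a range of 0.0270 to 0.771 for all alternatives. Of the 7 cholinergic transmitter genes with a probe set, 5 were tested, 2 were called higher and 2 lower. The list's median was -0.68 (0.88 with the median of all probe sets made equal), its mean 0.79 and its direction in the test upward, and it did not differ from other genes (camera, adjusted p = 0.795). Prima1, the anchor of acetylcholinesterase, had no array at 50 (5.05 in IP), and Isl1 was at the lowest level of the table in both fractions. Chat itself was not analysed here.

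Of the nicotinic acetylcholine receptor subunits, only Chrna3, Chrnb4 and Chrna4 passed the filter on dim probe sets, out of 15 with a probe set. Chrna3 (110834_at) stood at 11.40 ± 0.24 in IP and 7.38 ± 0.03 in UB, and Chrnb4 (108015_at) at 11.21 ± 0.32 and 7.28 ± 0.06 (log2 fold changes 4.0 ± 0.13 and 3.92 ± 0.18, adjusted p = 7.32e-06 and 2.65e-05). Chrna4 (11438_at) had the level 5.94 on all 3 IP arrays and 6.84 on all 3 UB arrays, a log2 fold change of -0.91 (adjusted p = 3.11e-08). Its call as lower rested on these ties and on the scaling, since the value was 0.64 with the median of all probe sets made equal and -0.02 with quantile normalization. The other 12 were under 50 on all arrays, so their folds cannot be given. Chrnb2 was at 4.18 in IP and 3.88 in UB, and Chrna5, Chrna6 and Chrnb3 at 3.87, 2.80 and 2.40 in IP and at the lowest level of the table in UB. Chrna1, Chrna2, Chrna7, Chrna9, Chrnb1, Chrnd, Chrne and Chrng were at or near the lowest level in both fractions. The list as a whole was not called (camera, adjusted p = 0.514), but was called higher with the control offset taken per array (adjusted p = 0.0309) and with no filter (0.0114), over a range of 0.0114 to 0.662 for all alternatives. The HCN channels carry the pacemaker current, and Hcn2 and Hcn3 were tested. Hcn3 (15168_at) was 1.84-fold higher in IP, at 7.92 on all 3 IP arrays against 7.02 ± 0.05 in UB (log2 fold change 0.88 ± 0.03, adjusted p = 5.69e-06). Hcn2 (15166_at) was 2.34-fold lower, at 7.61 ± 0.32 against 8.82 ± 0.64 (log2 fold change -1.22 ± 0.38, adjusted p = 0.0371). The Hcn2 call was lost without IP replicate 1, 2 or 3 and without UB replicate 2 or 3 (adjusted p from 0.0676 to 0.147), and with quantile normalization and with equal medians of the tested probe sets (adjusted p = 0.0786 and 0.0900, with a range of 0.000137 to 0.442 over all alternatives). Its value was 0.33 with the median of all probe sets made equal. The 3 muscarinic receptor genes with a probe set, Chrm1, Chrm3 and Chrm4, did not pass the filter.

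**Figure D2:**
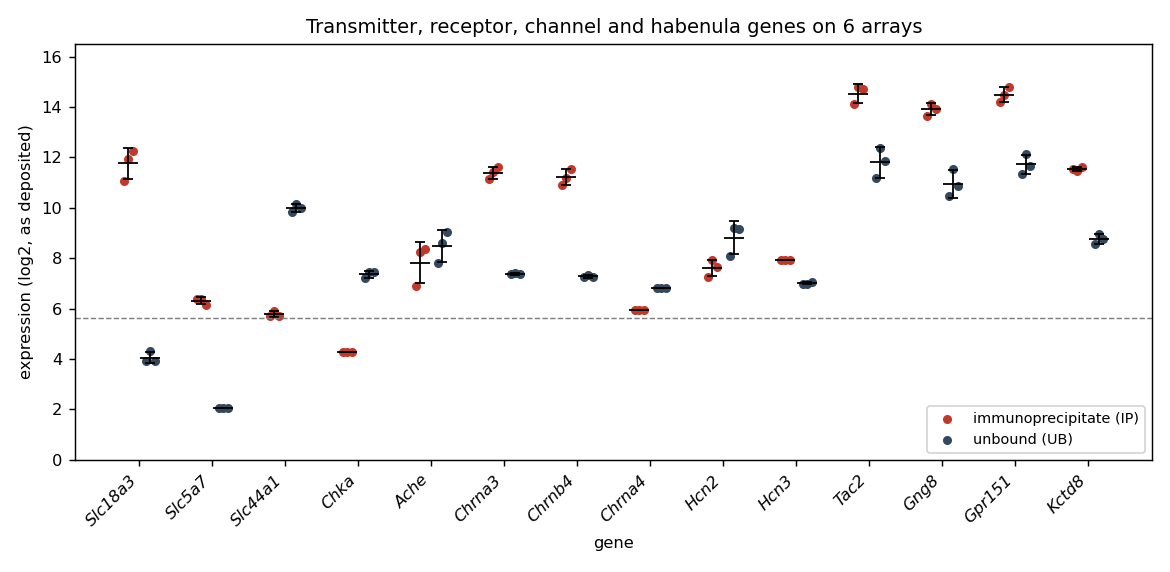
Deposited log2 expression (y axis) of 14 cholinergic, nicotinic, HCN and habenula genes (x axis) on the 3 IP arrays (red) and the 3 UB arrays (dark). Each point is an array, bars give the mean ± SD, and the dashed line marks the level of 50 (log2 5.644). Slc18a3 lay at 11.76 ± 0.62 in IP and 4.05 ± 0.22 in UB, while the arrays of Ache overlapped.

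Of 11 habenula markers, 10 were called higher and 1, the calcium-binding protein gene Calb2†, lower (median log2 fold change 2.47). Tac2, the neurokinin B precursor, was 6.56-fold higher, Gng8 7.68-fold, Gpr151 6.73-fold and the GABA-B receptor partner Kctd8 6.84-fold. The transcription factor genes Nhlh2†, Pou4f1† and Irx2† rose by log2 fold changes of 2.06, 1.74 and 2.66, Nwd2† and Kctd12b† by 2.22 and 2.47. Zic1† rose by 0.48, while Calb2 fell by 1.39. The list differed from other genes (camera with a preset correlation, adjusted p = 0.00413), but not with an estimated correlation (adjusted p = 0.329) or with the median of all probe sets made equal (adjusted p = 0.153) or with no filter on dim probe sets (adjusted p = 0.342). With equal medians Calb2 was at 0.16. Over all alternatives the adjusted p of that list ranged from 0.000322 to 0.342.

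Of the 8 dorsal medial habenula and peptide markers, Synpr was 8.63-fold higher in IP, and the cholecystokinin gene Cck 12.5-fold and Calb1 11.3-fold lower. Col16a1 was at least 1.99-fold lower, Wif1† and Adcyap1† were called lower as well (-1.50 and -0.45), and Tac1† and Il18† were not called (-0.46 and -0.59). That list was not called (camera, adjusted p = 0.250), and its median of -1.04 (-0.79 with dim members at their bounds) was 0.51 with the median of all probe sets made equal. All 5 tested lateral habenula markers fell, Vgf at least 48.2-fold, Htr2c at least 6.78-fold, Gap43 58.3-fold, Pcdh10 at least 3.92-fold and Syn2† 25.3-fold (median -5.86, or -4.66 at the bounds, camera adjusted p = 0.00544, with an estimated correlation adjusted p = 0.276). With no filter on dim probe sets that list was not called (adjusted p = 0.0515, with a range of 2.84e-07 to 0.276 over all alternatives). All 8 tested markers of thalamic neurons fell too, among them Necab1 at least 33.4-fold, Rgs16 at least 11.5-fold, the transcription factor gene Gbx2 at least 23.9-fold and the nuclear receptor gene Rora 39.1-fold (median -5.14, or -4.05 at the bounds, camera adjusted p = 0.00636, with an estimated correlation adjusted p = 0.276). Markers of hippocampal and cortical excitatory neurons parted. Nrgn was 6.46-fold higher in IP, with Neurod2† 5.47-fold and Neurod6† at least 2.63-fold higher. Dsp was at least 3.52-fold, C1ql2 at least 3.26-fold and Camk2a at least 1.25-fold lower, and Wfs1† was not called (-0.35). The adjusted p of that list was 0.589, and its median moved from -0.35 (-0.32 at the bounds) to 0.07 with quantile normalization and to 1.20 with the median of all probe sets made equal. The Nrgn call was lost without IP replicate 2, IP replicate 3 or UB replicate 3 (adjusted p from 0.0525 to 0.110, with a range of 1.64e-18 to 0.110 over all alternatives).

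Slc17a7, the vesicular glutamate transporter VGLUT1, was 8.87-fold higher in IP (9.26 ± 1.03 against 6.10 ± 1.22, adjusted p = 0.0235). Slc17a6, which encodes VGLUT2, was 1.85-fold lower in IP (12.35 ± 0.35 against 13.22 ± 0.29), and the glutamine transporter genes Slc38a1 and Slc38a2 were 2.30-fold and 1.55-fold lower. All of these 3 decreases turned into increases with the median of all probe sets made equal (0.67, 0.35 and 0.92 on the log2 scale). The Slc17a7 call was lost without IP replicate 2 or 3 or UB replicate 1 (adjusted p from 0.0531 to 0.0829), and the Slc17a6 call without IP replicate 1 or 2 or UB replicate 2 or 3 (adjusted p from 0.0512 to 0.120). The Slc17a6 call was also lost with equal medians of the tested probe sets (adjusted p = 0.0984, with a range of 0.00239 to 0.120 over all alternatives). Both the Slc17a7 and the Slc17a6 call held with the replicate number as a block and with both arrays of replicate 1 left out. The median of the vesicular glutamate release list was -0.76, its mean 0.11, its direction in camera downward and its adjusted p 0.690, and its median was 0.79 with the median of all probe sets made equal. All 5 tested GABAergic transmitter genes fell: the vesicular GABA transporter gene Slc32a1 at least 7.60-fold, Gad1 at least 30.7-fold, Gad2 at least 3.89-fold, Pvalb at least 23.2-fold and Abat† 3.05-fold (median -5.72, or -2.93 at the bounds, camera adjusted p = 0.0136, with an estimated correlation adjusted p = 0.276). That list lost its call with no filter on dim probe sets (adjusted p = 0.506) and with both arrays of replicate 1 left out (adjusted p = 0.0511, with a range of 6.19e-06 to 0.506 over all alternatives). Of 5 monoaminergic genes tested, Th, the tyrosine hydroxylase gene, was 4.80-fold higher, Ddc at least 23.1-fold, Maob 22.9-fold and Hdc at least 1.43-fold lower, and Maoa† was not called (-0.14). The adjusted p of the monoaminergic list was 0.302, and with equal medians of all probe sets it was called lower (adjusted p = 0.0254, with a range of 0.0254 to 0.813 over all alternatives).

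Among 12 tested neuropeptide genes, 2 rose and 8 fell. Tac2 was higher as given above and the opiomelanocortin gene Pomc† rose by a log2 fold change of 1.33. The somatostatin gene Sst was at least 5.87-fold, the neurotensin gene Nts at least 5.26-fold, the corticotropin-releasing hormone gene Crh at least 4.71-fold and the enkephalin gene Penk at least 4.08-fold lower. Tac1† and Cartpt† were not called (-0.46 and 0.47), and the list's adjusted p was 0.0861. It was called lower with the control offset per array (adjusted p = 0.000329), with equal medians of all (0.00194) or of the tested probe sets (0.0350), with quantile normalization (0.0164) and without UB replicate 2 (0.0449), over a range of 0.000329 to 0.306 for all alternatives. Only 3 of 19 genes of opioid, tachykinin and other peptide receptors passed the filter. The somatostatin receptor gene Sstr2 was 12.4-fold higher in IP and the nociceptin receptor gene Oprl1 1.8-fold higher. Tacr3, the neurokinin B receptor gene, was at least 1.65-fold lower, at the lowest level of the table on all 3 IP arrays (list adjusted p = 0.712).

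Of 22 potassium channel genes tested, 15 fell and 5 rose. Kcna1, Kcnc1, Kcnab1 and Kcnk2 were at least 14.1-fold, at least 13.4-fold, at least 10.4-fold and at least 5.94-fold lower. In all, 13 of the list were under 50 on all 3 IP arrays. The members that rose were Kcnip1†, a modulator of A-type channels (3.00), the large-conductance calcium-activated channel gene Kcnma1† (1.77), Kcnn1† (at least 1.14-fold, a call lost with levels under 50 raised to 50, adjusted p = 0.0931, with a range of 7.06e-09 to 0.0931 over all alternatives), the A-type channel gene Kcnd2† (1.43) and Kcnip3† (0.54), while Kcnk1† and Kcnn2† were not called (Kcnk1 was called higher with the replicate number as a block, adjusted p = 0.0117, with a range of 6.14e-05 to 0.751 over all alternatives). The potassium channel list differed from other genes (camera, adjusted p = 0.0109), but not with an estimated correlation (adjusted p = 0.382), with no filter on dim probe sets (adjusted p = 0.210) or with tied probe sets left out (adjusted p = 0.198, with a range of 1.37e-06 to 0.382 over all alternatives). Its median was -4.13, or -1.16 with dim members at their bounds. Of 10 voltage-gated calcium channel genes, 8 fell, among them Cacng2 at least 5.54-fold, the T-type channel gene Cacna1g at least 5.38-fold, Cacna2d1 at least 4.41-fold and Cacna2d3 at least 16.4-fold. Cacng5† and Cacna2d2† rose by 0.81 and 0.34 (list adjusted p = 0.146). The calcium channel list was called lower with the control offset per array (adjusted p = 0.000518), with equal medians of all probe sets (0.00486), with quantile normalization (0.0253) and with no filter (0.0323), over a range of 0.000518 to 0.324 for all alternatives. Of 8 sodium channel genes, Scn4b was at least 4.71-fold, Scn1a 7.54-fold, Scn2a 2.15-fold and Scn8a† 2.1-fold lower. Scn3b was at least 1.44-fold higher with Nalcn† and Scn2b† at 0.39 and 0.34, while Scn3a† was not called (0.39). The Scn2b call was lost without UB replicate 1 (adjusted p = 0.0570). The sodium channel list had an adjusted p of 0.860 and a median of -0.35, which was 1.20 with the median of all probe sets made equal, a scaling under which Scn2a and Scn8a were higher (0.45 and 0.52).

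Of 12 tested genes for GABA receptors and their partners, 8 fell, with the channel subunit genes Gabra4 at least 132-fold, Gabrd at least 15.8-fold, Gabrb1 51.2-fold and Gabrb2 at least 36.7-fold lower. The 3 that rose were the GABA-B receptor gene Gabbr1† (1.43) and the GABA-B partner genes Kctd8 and Kctd12b†, both also in the habenula list. A further partner gene, Kctd12†, was 2.64-fold lower (0.16 on the log2 scale with the median of all probe sets made equal), and Gabra2† was not called (-0.25). The list's adjusted p was 0.208, but it was called lower with the control offset per array (adjusted p = 0.000329), with equal medians of all probe sets (0.00179) and with quantile normalization (0.0423), over a range of 0.000329 to 0.662 for all alternatives. Among 8 ionotropic glutamate receptor genes, Gria3 was at least 13.7-fold, Grin2c at least 3.20-fold, Grik1 at least 6.87-fold, Grik3 at least 1.62-fold and Gria2† 5.38-fold lower. Gria4† rose by 0.45, and Gria1† and Grik5† were not called (0.07 and 0.69). Grik5 was called higher with the replicate number as a block (adjusted p = 0.00762, with a range of 0.00519 to 0.668 over all alternatives). The list of ionotropic glutamate receptor genes had an adjusted p of 0.250, but was called lower with the control offset per array (adjusted p = 0.0177) and with equal medians of all probe sets (0.00873), over a range of 0.00873 to 0.599 for all alternatives. Of the metabotropic glutamate receptor genes, Grm7 was at least 39.7-fold and Grm5 17.6-fold lower, and Grm2 and Grm3 were not called (0.30 and -0.22; list adjusted p = 0.514).

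Glial markers fell in IP almost without exception. All 14 tested astrocyte markers were lower, among them S100b at least 29.8-fold, Gjb6 at least 18.1-fold, the glutamate transporter gene Slc1a2 at least 15.4-fold and Ntsr2 at least 34.7-fold. All 13 tested oligodendrocyte markers were lower, among them Mog at least 32.7-fold, Aspa at least 25.9-fold, Ermn at least 57.5-fold and Opalin at least 25.6-fold. Mbp†, the myelin basic protein gene, stood at 7.12 ± 0.24 in IP against 13.59 ± 0.02 in UB. Of 6 oligodendrocyte precursor markers, 5 fell (Olig1 107-fold, Gpr17 at least 4.79-fold, Olig2 at least 4.14-fold, Pdgfra at least 1.42-fold and Ptprz1† 6.06-fold) and Lhfpl3† was not called (-0.23). Of 7 microglia markers, 6 fell, among them C1qb at least 5.72-fold, Ctss 50.9-fold, Csf1r at least 3.82-fold and Tyrobp at least 3.47-fold, and C1qa† was not called (0.88). All 4 lists differed from other genes in camera with a preset correlation, with adjusted p = 5.47e-05 for astrocytes and for oligodendrocytes, 0.0136 for precursors and 0.00521 for microglia. With an estimated correlation the adjusted p was 0.297 for oligodendrocytes and 0.276 for each of the other 3. The medians of the 4 lists were -5.06, -6.64, -4.77 and -5.33, or -3.16, -4.68, -2.15 and -1.79 with dim members at their bounds.

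Other cells of the tissue were represented by fewer genes. Of 7 ependymal and choroid plexus markers, Ccdc153 was at least 56.2-fold, Calml4 at least 24.3-fold, Tmem212 at least 7.58-fold, Rarres2 at least 1.67-fold and the transthyretin gene Ttr† 12.1-fold lower in IP. Sostdc1† was 13.0-fold and Otx2† 2.35-fold higher (list adjusted p = 0.526). The list was called lower with the control offset per array (adjusted p = 0.000170) and with equal medians of all probe sets (0.0140), over a range of 0.000170 to 0.869 for all alternatives. The call of Ttr was lost with both arrays of replicate 1 left out (adjusted p = 0.0519) and that of Rarres2 with levels under 50 raised to 50 (adjusted p = 0.0986), with ranges of 8.15e-33 to 0.0519 and 1.81e-54 to 0.0986 over all alternatives. Lower ends this small are no measure of evidence from 3 arrays per fraction. Choroid plexus genes differed in how even they were among the UB arrays. Ttr was 15 on UB replicate 1 and 13.37 and 13.87 on the others, and Kcnj13† was 7.76 against 4.25 and 4.26, whereas Sostdc1 was 6.86, 6.86 and 6.72 and Otx2 8.78, 8.63 and 8.50. Slc2a1 was the only endothelial or mural marker to pass the filter and was 3.16-fold lower. Bpgm was the only blood cell marker and was not called (0.88 ± 0.33, adjusted p = 0.0657), but was called higher with the replicate number as a block (adjusted p = 0.0225, with a range of 0.00141 to 0.249 over all alternatives). Of 16 pan-neuronal markers, 10 fell, among them Gap43, Map2 at least 4.04-fold, the neurofilament gene Nefl 5.41-fold, Syn1 3.40-fold and Syt1† 3.27-fold, the last a call lost without IP replicate 1 or 3 or UB replicate 2 or 3 (adjusted p from 0.0648 to 0.107). The Syt1 call was also lost with quantile normalization (adjusted p = 0.0593) and with equal medians of the tested probe sets (adjusted p = 0.0519), over a range of 3.63e-08 to 0.772 for all alternatives. Rbfox3† and Elavl4† rose by 0.88 and 0.68, and Eno2†, Syp†, Elavl3† and Uchl1† were not called. The adjusted p of the pan-neuronal list was 0.211, and its median of -1.22 was 0.34 with the median of all probe sets made equal. With quantile normalization that list was called lower (adjusted p = 0.0145, with a range of 0.0145 to 0.599 over all alternatives). Of 8 immediate early genes, 6 fell, with Dusp1 28.3-fold, Jun at least 11.9-fold, Egr1 15.1-fold and Fos† 8.77-fold lower. Btg2 and Arc† rose, Btg2 at least 1.49-fold and Arc at least 4.11-fold (list adjusted p = 0.589).

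**Figure D3:**
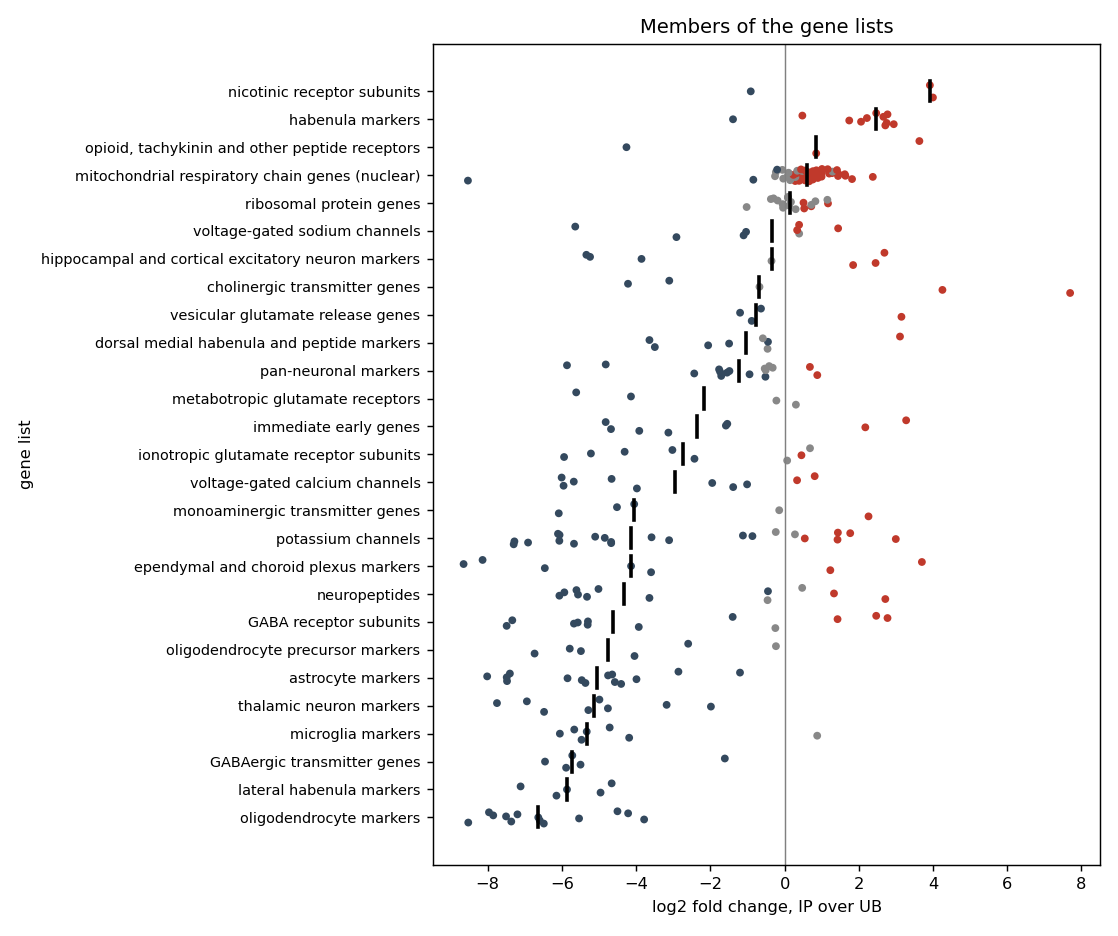
Log2 fold change of IP over UB (x axis) for each tested member of the 27 gene lists with 3 or more tested members (y axis, ordered by median). Points are genes, red where called higher, dark where called lower and grey where not called, and black bars are list medians, from -6.64 for oligodendrocyte markers to 3.92 for nicotinic receptor subunits. Folds of genes under 50 on all arrays of a fraction are drawn as fitted, although only bounds are known for them, and making the median of all probe sets equal would move every point to the right by 1.55.

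Nuclear genes of the mitochondrial respiratory chain were more often higher than lower. Of 57 tested, 41 rose, 3 fell and 13 were not called, with a median log2 fold change of 0.61. The size and the numbers moved with the scaling: 34 rose and 5 fell with quantile normalization (median 0.37), 28 rose with the control offset per array, and 56 rose with the median of all probe sets made equal (median 2.16). Ndufa7 was 5.20-fold, Cox8a 3.53-fold and Ndufaf3 3.11-fold higher, the last an assembly factor of complex I that the name pattern of the list also took. The 3 that fell were Cox6a2, a cytochrome oxidase subunit gene known from muscle, at least 43.7-fold, Cox7a1† (-0.84) and Uqcrc2† (-0.20). The list differed from other genes (camera, adjusted p = 5.45e-06), but not with an estimated correlation (adjusted p = 0.317) or with no filter on dim probe sets (adjusted p = 0.210, with a range of 1.02e-07 to 0.317 over all alternatives). The call of Ndufa7 was lost without IP replicate 2 or 3 or UB replicate 1 or 3 (adjusted p from 0.103 to 0.149). That of Cox8a was lost without any array but IP replicate 1 (adjusted p from 0.0537 to 0.121). Of 18 ribosomal protein genes, Rpl5 (1.17), Rpl23† (0.72), Rpl15† (0.53) and Rpl8† (0.51) rose and 14 were not called, among them Rps27l (1.15), Rpl22 (-1.02) and Rps15 (0.83; list adjusted p = 0.146). The calls of Rpl23, Rpl15 and Rpl8 were lost without UB replicate 1 (adjusted p = 0.0919, 0.0676 and 0.0581), those of Rpl23 and Rpl8 also without IP replicate 3 (0.125 and 0.0512), and that of Rpl23 also without UB replicate 2 or 3 (0.0672 and 0.0517). Rpl15 and Rpl23 were also not called with both arrays of replicate 1 left out (adjusted p = 0.0564 and 0.137), nor Rpl15 with quantile normalization (adjusted p = 0.191). Their ranges over all alternatives were 2.33e-05 to 0.191 and 0.000264 to 0.137. Rpl22 was called lower with the control offset per array (adjusted p = 0.00163, with a range of 0.00163 to 0.274 over all alternatives). With equal medians of all probe sets 17 of the 18 genes were called higher (median 1.70 in place of 0.15), and with equal medians of the tested ones 11 (median 0.49). Rps27l and Rps15 were called higher with the replicate number as a block (adjusted p = 0.0116 and 0.0411), with ranges of 0.000352 to 0.257 and 0.00281 to 0.408 over all alternatives. Adjusted over the list alone, the numbers of genes called were those given over all probe sets, except that the dorsal medial habenula list had 6 lower in place of 5, the neuropeptides 9 in place of 8, the potassium channels 16 in place of 15, and the ribosomal protein genes 3 higher in place of 4.

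The 10 called genes with the largest fitted increases, Slc18a3 among them, were under 50 on every UB array, so only lower bounds of their folds are known and their order is not. The sialyltransferase gene St6galnac1 was at least 11.1-fold higher in IP, the glutathione peroxidase gene Gpx2 at least 15-fold, Gm17750 at least 34.0-fold and the chemokine gene Cxcl11 at least 21.5-fold. The signalling gene Wnt11 was at least 7.34-fold higher, Wfikkn2 at least 6.99-fold, Crnde at least 5.56-fold, Clec18a at least 5.48-fold and Nfam1 at least 3.43-fold. The 10 with the largest fitted decreases were under 50 on all 3 IP arrays, and some genes outside them, such as Olig1 and Gabra4 above, had a larger known fold. The 10 were Ankrd34b at least 56.5-fold, the troponin gene Tnnt1 at least 101-fold, Ctxn3 at least 50.6-fold, the retinaldehyde dehydrogenase gene Aldh1a1 at least 36.2-fold, Slc25a18 at least 22.6-fold, and Ccdc153, Cox6a2, Mog, Calml4 and S100b as given above.

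Every p here rests on 3 arrays per fraction, and 587 of the tested probe sets had 1 value on all 3 arrays of both fractions. Other probe sets lend these a spread, but with little weight (0.651 prior degrees of freedom). Their SE was therefore very small, such as 0.0042 for Htr2c and 0.0079 for S100b. Ties in 1 fraction, as for Hcn3 in IP (SE 0.027), lowered the SE as well. The p of tied probe sets does not measure their precision. With the control offset taken per array, the adjusted p of genes that changed their call followed the size of the change and hardly their own spread. Adcyap1†, with an SE of 0.024 in the main fit, had an adjusted p of 0.196 at a change of -0.45. Rps27l, with an SE of 0.45, had an adjusted p of 0.000352 at 1.15. Those p are no measure of a gene's own precision. With the control offset taken per array, the calls of Slc38a2, Adcyap1†, Cacna2d2†, Gria4†, Kcnip3†, Nalcn†, Rpl15†, Rpl8†, Scn2b†, Uqcrc2† and Zic1† were lost (adjusted p from 0.0558 for Slc38a2 to 0.572 for Uqcrc2). With equal medians of all probe sets those of Syn1, Slc2a1, Abat† and Syt1† were lost (adjusted p = 0.599, 0.766, 0.412 and 0.772). Besides the genes whose gained calls are given above, C1qa†, Cartpt†, Elavl3†, Eno2†, Gabra2†, Gria1†, Grm2, Kcnn2†, Lhfpl3†, Scn3a†, Syp† and Tac1†, given as not called, were called with the same sign under at least 1 alternative.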

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

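The tests of the 3 patterns below and those with other splits of the arrays were chosen only after the results were seen.

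The poly-A control probe sets, which no comparison used, were higher in IP than in UB. Their median difference was 1.336 on the log2 scale (24 of 24 higher, from 0.887 to 3.91), and for 22 of them all 3 IP arrays lay above all 3 UB arrays. Their medians were 7.85, 8.98 and 8.34 on the IP arrays and 7.07, 6.86 and 6.48 on the UB arrays. The labels do not say whether these controls were added or in what amount, so the difference was not used for scaling and no explanation of it was tested.

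More probe sets were at least 2-fold lower in IP (2513) than higher (1285). Folds computed from levels under 50 are argued against as the whole cause. With such levels raised to 50, the share of 2-fold calls that were higher was 35.5% against 33.8%. That does not reach levels the background correction may have pushed from above 50 to under it, so its part stays open. Of the lower calls, 1302 were under 50 on all IP arrays, and of the higher calls, 297 were under 50 on all UB arrays. The 7011 probe sets with signal on all 6 arrays were more even (954 higher and 1129 lower). Cell types of the tissue that the tag does not capture may account for part of the excess of lower calls. Of the tested glial markers, 95% (38 of 40) were at least 2-fold lower, among them Mog and S100b. A difference in hybridization or scanning between the fractions stays open, since the shift of 0.344 on the log2 scale that would balance the numbers lies between 3 SE of the control offset over control probe sets (0.093) and 3 SE over arrays (0.636). A difference in the amount of RNA per fraction, which array values do not carry, stays open and was not tested.

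Replicate 1 stood apart in both fractions: 294 of 7011 probe sets with signal on all arrays were off by more than 1 on the log2 scale from the other arrays of the fraction in IP replicate 1 and 88 in UB replicate 1, against at most 48 in any other array. Another makeup of the dissected tissue was taken to move UB and not IP for genes at a like level in both, a premise that was not tested. The r between the fractions across such probe sets, which are not independent replicates, was 0.659. It was positive in each preparation: over the 7011 probe sets it was 0.653, 0.541 and 0.292 for replicates 1, 2 and 3. The r is thus not particular to replicate 1 and cannot decide the question, so another makeup stays open. Shorter cDNA or RNA in replicate 1 may be the source, since the gap from the 3' to the 5' probe set was largest in replicate 1 in 4 of 4 comparisons of Gapdh and Actb, from 2.03 against 1.44 and 1.53 for Gapdh in UB to 3.68 against 3.43 and 3.26 for Actb in UB. These are 2 genes in paired fractions, so the comparisons are not independent. Gaps of the poly-A controls were mixed. In UB, that of DapX was narrowest in replicate 1 (11.98 at 3' and 6.81 at 5', against 11.67 and 4.76 in replicate 3). That of LysX was widest there (8.89 and 2.69, against 8.62 and 2.69 in replicate 3). The choroid plexus genes Ttr and Kcnj13 were higher on UB replicate 1, and so was Clic6† (6.34 against 4.11 and 4.19). Kl† and Folr1†, under 50 on all arrays, leaned the same way. Sostdc1 and Otx2, both higher in IP, were even among the UB arrays. Any biological difference between the preparations stays open as well and was not tested.

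Members of the hippocampal and cortical list (Nrgn, Neurod2 and Neurod6) were higher in IP, which hippocampal or cortical tissue in the IP could have caused. That stays open: of the 8 other members with a probe set, 7 were under 50 in IP, Dsp, C1ql2 and Camk2a among them, and only 1, Wfs1, had signal on all 6 arrays. The level that such tissue would give the dim members is not known. Expression of Nrgn, Neurod2 and Neurod6 in the tagged neurons stays open as well, and no test of it was run.

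With 3 arrays against 3, the 10 splits of the arrays cannot give a share under 0.05. For each of the 4 counts (2772 probe sets higher, 3900 lower, 1285 and 2513 at least 2-fold), 1 split, the real one, gave as many, and the highest of the others was 0. Of those others, 3 part all 3 pairs of equal replicate numbers, as the real split does, and gave 0, while the remaining 6 keep a pair together. Each of the other splits mixes IP and UB arrays within a group, so the large differences between fractions widen the spread there. Their counts of 0 therefore say nothing about chance.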

How the results depend on the processing

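The tests with both arrays of replicate 1 left out, with tied probe sets left out, with levels under 50 raised to 50 and with equal medians of the tested probe sets were chosen only after the result was seen. The 4 counts of probe sets stayed within 1.5 times their values in all alternatives but the following. With equal medians of all probe sets, which moves every fold by 1.55 on the log2 scale, 6640 probe sets were higher and 1585 lower, 5491 and 1238 of them by at least 2-fold. With no filter 8557 were higher and 5998 lower, of 17306 tested. With a filter at 200, of 6358 tested, 2437 were lower and 1453 at least 2-fold lower. With equal medians of the tested probe sets, a shift of 0.34, 1993 were at least 2-fold higher. Among the alternatives within 1.5 times, quantile normalization gave 1894 at least 2-fold higher and 1973 lower. Also within 1.5 times, without each array in turn 2053 to 3151 were higher, 3315 to 4139 lower, 973 to 1526 at least 2-fold higher and 2259 to 2760 at least 2-fold lower. The glial threshold was negative (-1.53) and so could not change the count of probe sets higher. Of the 27 lists, 10 were called, and 10 to 11 without each array in turn. With the control offset per array 16 were called, and the cause was not tested. In that setting the adjusted p of genes that changed their call followed the size of their change, as given above. With an estimated correlation in camera 0 were called. That version did not call the simulated shifted list either, but there the adjustment was over 200 lists in place of 27. The replicate block changed the calls of Ache, Bpgm, Rps27l, Rps15, Grik5 and Kcnk1 and no other call of a named gene or list. Named genes that lost a call without an array in turn thus kept it with the block. With both arrays of replicate 1 left out, all of these but Rpl15 and Rpl23 kept it as well. Of named genes, 28 values reversed. Through the shift itself these were, with equal medians of all probe sets, Chrna4 0.64, Hcn2 0.33, Slc38a1 0.35, Slc17a6 0.67, Slc38a2 0.92, Grm3 1.33, Scn2a 0.45, Scn8a 0.52, Kctd12 0.16, Adcyap1 1.11, Calb2 0.16, Tac1 1.10, Il18 0.97, Wif1 0.059, Cox7a1 0.71, Uqcrc2 1.35, Elavl3 1.23, Eno2 1.04, Syp 1.02, Uchl1 1.14, Gabra2 1.31, Kcnn2 1.32, Lhfpl3 1.32, Lhx2 0.28, Maoa 1.41 and Wfs1 1.20, and, with equal medians of the tested probe sets, Uqcrc2 0.14. With quantile normalization Kcnn2 was at 0.22, and the cause was not tested. Over all alternatives, other values of named genes lost a call in 64 cases and gained it in 60, and in 3827 cases they were called, or not called, as before. For lists these numbers were 18, 20 and 524. The mean over a gene's probe sets was not run, as each gene had 1. Signal over background limited the folds of the 1374 tested probe sets under 50 on all IP arrays and the 352 under 50 on all UB arrays.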

Other observations

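The gene families in this part and their genes, Wnt11 and Col16a1 apart, were chosen after their values were seen, and so were their tests. Of 12 tested transcription factor genes of the Iroquois, Pou, Lhx and Zic families, 10 were called higher in IP, among them Irx6 at least 2.56-fold, Zic4 8.75-fold, Irx3 7.72-fold and Irx5 6.58-fold, and Lhx2 was 2.42-fold lower (0.28 on the log2 scale with equal medians of all probe sets). The family median was 2.44, or 1.98 with dim genes at their bounds (camera, adjusted p = 0.0272, with an estimated correlation adjusted p = 0.656). Of 6 Wnt and Frizzled genes, 4 were higher and 2 lower: Fzd1 was 9.57-fold, Fzd9 at least 4.30-fold and Wnt11 at least 7.34-fold higher, while Wnt4 was at least 9.62-fold and Fzd5 at least 1.93-fold lower (adjusted p = 0.492). Of 18 cadherin and protocadherin genes, 14 were lower, among them Pcdh19 at least 9.88-fold and Cdh11 at least 10.3-fold, and Cdh22 and Cdh8 were 5.18-fold and 2.16-fold higher (median -1.58, -0.93 at the bounds and -0.02 with equal medians of all probe sets, adjusted p = 0.0310, with an estimated correlation adjusted p = 0.570). Of 30 proteasome genes, 14 were higher and 3 lower (8 and 1 with the control offset per array, 11 and 6 with quantile normalization, 30 and 0 with equal medians of all probe sets). Among them were Psmb8 at least 1.89-fold, Psmb9 at least 2.45-fold and Psma7 1.39-fold higher, the last a call lost with the control offset per array (adjusted p = 0.163, with a range of 3.06e-08 to 0.163 over all alternatives). The family median was 0.40, or 0.25 with quantile normalization (camera, adjusted p = 0.0272, with an estimated correlation adjusted p = 0.570). All 3 tested collagen genes were lower, Col9a3 at least 1.11-fold, Col4a1 at least 1.06-fold and Col16a1 at least 1.99-fold (median -3.58, -0.15 at the bounds, adjusted p = 0.0310, with an estimated correlation adjusted p = 0.570). A shift of 0.34 on the log2 scale, as with equal medians of the tested probe sets, would take away the bounds of Col9a3 and Col4a1. The other 15 families were not called (adjusted p from 0.336 to 0.972).

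The control probe set for the murine B1 repeat stood at 11.69 ± 0.20 (SD, n = 3) in IP and 15.65 ± 0.05 in UB, 15.5-fold lower in IP, while the B2 repeat differed by -0.33 and -1.67 on its 2 probe sets and 18S ribosomal RNA by -0.23 to -0.59 on 3. The B2 probe set with -0.33 stood at 15.35 in IP and 15.68 in UB. That is near the highest values of the arrays (16.18 to 16.49), which limits what its small difference can show. With equal medians of all probe sets the B2 and 18S differences other than -1.67 would change sign, since that shift is 1.55.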
